A study of Mus musculus with 9 samples.

How the data were processed

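Total RNA from mouse normal thymus, thymus tumor and thymus tumor described as resistant to XIST was labelled with biotin and hybridised to the Affymetrix Mouse430_2 array, per the labels' protocols. Each of the 3 groups held 3 arrays. The labels do not say whether the arrays of a group came from separate animals, so p-values measure only the spread between these arrays, which may be technical.

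The deposited values are linear intensity values, 1 per probe set and array, made with MAS5, per the submitters' processing notes. The MAS5 version, the scaling target and the detection calls are not given in the sources used here. In the table itself the trimmed mean, leaving out 2% of the values at each end, was 100.03 in every array, which is the form of a global scaling. The table held 45101 probe sets. The gene table supplied with the platform gave 1 symbol to 34945 of them and several symbols to 932. It did not list 9160, and 64 were control probe sets. Genes were matched by gene identifier to the RefSeq gene table of assembly GRCm38.p6. That match covered 18032 of 18193 symbols, and 161 had none. The reference table gave only the chromosome of each gene and the order of genes along it.

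For the tests, values under 1 were set to 1 and log2 was taken, with no further normalization between arrays. A probe set was kept when at least 3 of the 9 arrays reached that array's own median. Of the probe sets with 1 symbol, 20917 passed, and the probe set with the highest mean log2 signal stood for its gene, which left 11671 genes. Among these, 5427 had more than 1 probe set past the filter. Probe sets with several symbols or none and the control rows stayed out. One linear model with a mean per group was fitted to all 9 arrays in limma 3.58.1 under R 4.3.3, with 6 residual degrees of freedom and empirical Bayes moderation with an intensity trend. Contrasts were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes with an adjusted p under 0.05 were called. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

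Before the data were examined, 33 gene lists with 645 genes were fixed, together with the tests, the alternatives and the rule for named genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The self-contained test fry was an alternative. The rule names, per comparison, the 10 largest increases and the 10 largest decreases among called genes whose 2 groups do not overlap. It adds up to 4 called members with the largest change from each list described, and Xist and Satb1 in any case. Genes with a Rik or Gm symbol were passed over without replacement. All genes of the X chromosome were tested against the other genes with camera, adjusted over the chromosomes.

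Without detection calls, a gene under the array median on all 3 arrays of a group was treated as having only a bound there. Its change is given as "at least N-fold", from the mean log2 signal of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the gene's own log2 signal and the array median. No fold is given where both groups are that dim or the bound is under 1. Medians of gene lists use the fitted changes unless bounds are named. Values for single probe sets of Xist and Satb1 beyond the brightest come from a fit of all probe sets without the filter, with p-values adjusted over all of them.

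The poly-A spike-in control rows split the arrays. In 4 arrays (normal thymus 1, tumor 1, resistant tumor 1 and resistant tumor 2) their mean signal was 2.00 to 3.15, and in the other 5 it was 127 to 216. Each set of arrays held all 3 groups, so every comparison was repeated with the set as a block and within each set, and camera was run with the block at both the preset and an estimated correlation. This was chosen after seeing the data. The 64 control rows of tumor 1 stood in another order than in the other arrays. Their correlation with the mean of the others was -0.295 as deposited and 0.907 after sorting by row name, against 0.957 for this array's remaining rows as deposited. The set of each array was read after that sorting, and control rows entered no test.

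Checks on simulated data used 11671 genes for the comparison of resistant tumor with tumor. The model recovered 59.2% of changes of 1 on the log2 scale and 93.6% of changes of 3, and 4.36% of its calls were false. Camera called 50 of 50 shifted lists and 2 of 100 unshifted ones. The simulated genes varied independently and without spike-in sets. These checks therefore say nothing about lists of correlated genes, such as the fibroblast and stromal list with an estimated correlation of 0.682.

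The alternatives tried were quantile normalization, equal array medians, adding 50 before the log, no filter, a stricter filter at the 75th percentile, no intensity trend, the mean over probe sets, all probe sets, only the 2 groups compared, the replicate number as a block, array weights, a minimum change of 1 on the log2 scale, and leaving out each array in turn. The genes tested stayed those chosen on all 9 arrays where arrays were left out.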

Results

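Gene expression was measured in mouse normal thymus, in thymus tumors and in thymus tumors that the labels call resistant to XIST, the long noncoding RNA that silences an X chromosome. Each group comprised 3 Affymetrix arrays, and values are deposited MAS5 signals in arbitrary units. The design asks how tumors differ from normal thymus and how resistant tumors differ from the other tumors. Median signals per array were 13.9 to 25.8, and 5.48% to 14.5% of the values of an array lay below 1. Arrays without poly-A spike-in signal had medians of 23.6 to 25.8, and arrays with it had medians of 13.9 to 17.8. The ratio of the Actb 3' probe set to its 5' probe set, a sign of RNA integrity, was 1.63 to 3.16 over the 9 arrays, with the highest values in tumor 2 (3.16) and resistant tumor 3 (2.64). The number of arrays limits the precision of every value.

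The first principal component of the tested genes held 66.9% of the variance and separated normal thymus from both tumor groups. The second held 18.4% and followed the spike-in sets of arrays rather than the groups. The third, with 5.02%, separated resistant tumors from tumors. Correlations of log2 signals were 0.877 to 0.918 between normal thymus and either tumor group. Within a spike-in set they were 0.960 to 0.967 between tumors and resistant tumors, and 0.961 to 0.977 between arrays of the same group.

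**Figure D1:**
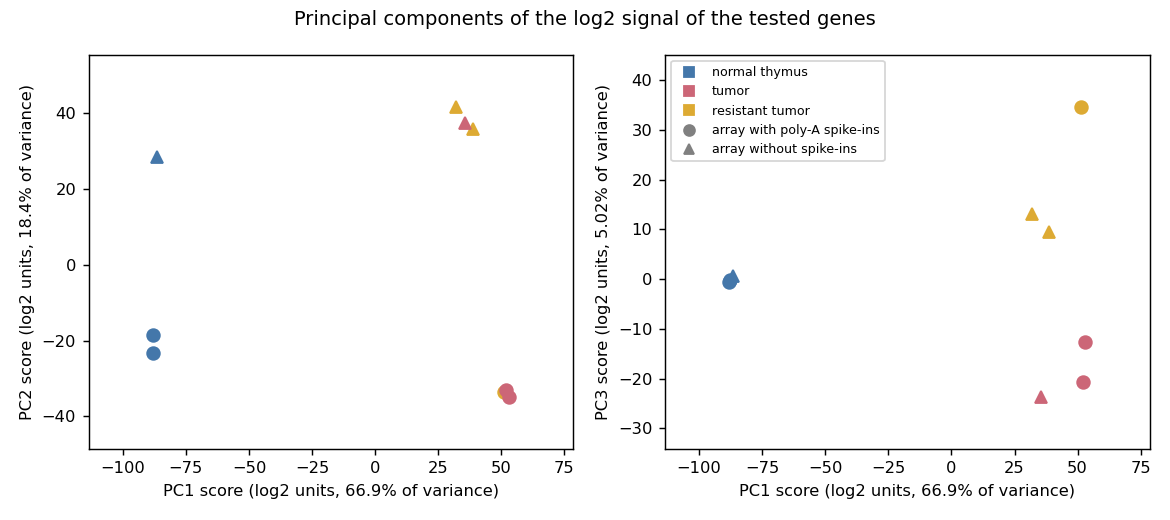
Scores of the 9 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in log2 units, with colors for the group and symbols for the presence of poly-A spike-in signal. Normal thymus lies apart on the first component (66.9% of variance), and the second (18.4%) follows the spike-in sets.

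Tumors differed from normal thymus first in genes of thymocytes and of the thymic epithelium. Prss16 and Psmb11, a protease and a proteasome subunit of cortical thymic epithelial cells, were at least 147-fold (adjusted p = 2.55e-05) and at least 32.5-fold lower (adjusted p = 7.98e-06). Pax1, a transcription factor of the thymic epithelium, was at least 22.6-fold lower, and Tbata was at least 124-fold lower. The coreceptor genes Cd8a and Cd8b1 were at least 125-fold and at least 156-fold lower, and the adhesion receptor gene Cd2 at least 28.4-fold lower. Igkv8-30, Fgf13 and Jakmip1 were at least 62.1-fold, 18.6-fold and 68.6-fold lower. Among the largest increases, Fbp1, which encodes a gluconeogenic enzyme, rose by 5.84 ± 0.29 on the log2 scale (SE, n = 3 arrays per group, limma adjusted p = 8.81e-07). Rnd2 rose by 5.73 ± 0.30, Stc1 by 5.49 ± 0.36, H2-Bl by 5.37 ± 0.16 and Adamts20 by 5.07 ± 0.24. Kcnk1, Pde9a and Sall3 were at least 9.53-fold, 7.86-fold and 2.34-fold higher.

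In total, 4943 of 11671 genes were called in tumor against normal thymus by limma, 2714 higher and 2229 lower. Of these, 2529 changed by at least 1 on the log2 scale. With the spike-in set as a block the count was 6854, all 4943 genes among them, and 4942 had the same sign within both sets. For 4913 of these calls the groups did not overlap, which by itself fixes the sign within each set. The groups did not overlap in 55.3% of the tested genes, where chance gives 10%. Setting the array medians equal moved the median change of all genes from 0.05 to 0.24 and left 2287 calls.

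Lists of T cell genes were lower in tumors. Each list's median log2 change is followed in brackets by its medians within the arrays without and with spike-ins. In the T cell receptor complex and signalling list, 14 of 19 tested genes fell and none rose (15 lower adjusted over the list alone), with a median of -1.85 [-1.80, -1.89]. This list was called with an estimated correlation too (camera adjusted p = 3.59e-08, and 0.0256 with an estimated correlation), but not with both that and the spike-in set as a block (adjusted p = 0.0605). Besides Cd8a, Cd2 and Cd8b1, Cd6 was at least 22.7-fold lower. Among genes of double-positive thymocytes, the stage that carries both coreceptors, 11 of 17 fell and 2 rose (11 and 3 adjusted over the list alone), with Ccr9 at -7.37 ± 0.59 and Cd4 at -6.00 ± 0.40. That list had a median of -1.01 [-1.10, -1.23] and an adjusted p of 5.75e-05, and 0.0858 with an estimated correlation. Of the genes of mature single-positive T cells, 16 of 18 fell (16 adjusted over the list alone), with Ms4a4b at least 20.3-fold, Ikzf2 at least 35.3-fold and Ccr7 at least 4.96-fold lower and Gimap8 at -5.19 ± 0.26. Here the median was -2.54 [-3.01, -2.22], or -2.42 with genes at their bounds, and the adjusted p was 2.65e-09, and 0.0614 with an estimated correlation. Notch targets moved the other way, with 9 of 13 higher and 2 lower (9 and 2 adjusted over the list alone). Dtx1 rose by 3.71 ± 0.19, Ptcra, the pre-T cell receptor alpha chain, by 3.01 ± 0.12 and Nrarp by 2.90 ± 0.12, and Heyl was at least 6.32-fold higher. The Notch list had a median of 1.61 [1.44, 1.70] and an adjusted p of 0.000405, and 0.137 with an estimated correlation. In the list of early thymocyte genes 7 of 19 rose and 3 fell (7 and 3 adjusted over the list alone), with Lmo1, a T cell oncogene, at 4.2 ± 0.38 and Il7r at -3.79 ± 0.26. As a whole it was not called (adjusted p = 0.447), and its median of -0.21 and mean of 0.28 differed in sign.

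Growth-related lists rose. Among MYC targets and nucleolar genes 22 of 23 rose and 1 fell (22 and 1 adjusted over the list alone), with Cad at 1.75 ± 0.15, Nolc1 at 1.40 ± 0.13, Myc at 1.27 ± 0.12 and Polr1b at 1.23 ± 0.18. Its median was 0.88 [0.79, 0.82] and its adjusted p 1.42e-07, and 0.127 with an estimated correlation. DNA replication genes rose in 18 of 28 cases and none fell (19 higher adjusted over the list alone), led by Tk1 at 1.22 ± 0.14 and Gins2 at 1.03 ± 0.15, with a median of 0.54 [0.58, 0.49] and an adjusted p of 0.000166, and 0.183 with an estimated correlation. The cell division list was not called (adjusted p = 0.184), with 2 genes higher, 2 lower and 20 not past the test (1 and 2 adjusted over the list alone). Hypoxia and glycolysis genes rose in 16 of 20 cases (16 adjusted over the list alone), with Vegfa at 2.28 ± 0.18, Egln3 at 2.19 ± 0.22, Ndrg1 at 2.09 ± 0.41 and Pfkl at 2.06 ± 0.23. Their median was 1.32 [1.27, 1.32] and the adjusted p 1.26e-05, and 0.267 with an estimated correlation. Of the ribosomal protein genes 6 of 19 rose (4 adjusted over the list alone), Rps6 by 0.76 ± 0.11, with a median of 0.22 [0.04, 0.32] and an adjusted p of 0.00463, and 0.483 with an estimated correlation.

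Markers of other cell types moved in both directions. Of 21 thymic epithelial markers 18 fell (18 adjusted over the list alone), with a median of -2.75 [-2.39, -3.57] (adjusted p = 2.65e-09, and 0.0385 with an estimated correlation, or 0.0605 with the spike-in set as a block as well). Antigen presentation genes of MHC class II fell in 8 of 13 cases (8 adjusted over the list alone), H2-Eb1 by -4.31 ± 0.24 and Cd74 by -3.60 ± 0.30, with a median of -2.36 [-1.97, -2.55], or -1.32 at bounds (adjusted p = 0.000106, and 0.127 with an estimated correlation). B cell markers fell in 10 of 12 cases (10 adjusted over the list alone), Cd79b at least 6.28-fold, with a median of -2.10 [-1.11, -2.30], or -1.36 at bounds (adjusted p = 0.000153, and 0.183 with an estimated correlation). Dendritic cell markers fell in 11 of 13 (11 adjusted over the list alone), Cd83 at least 25.3-fold, with a median of -1.67 [-1.19, -1.78], or -1.06 at bounds (adjusted p = 0.000129, and 0.0614 with an estimated correlation). Neutrophil markers fell in 7 of 10 (7, and 1 higher, adjusted over the list alone), Ngp at least 10.5-fold, with a median of -3.79 [-1.82, -4.41], or -1.78 at bounds (adjusted p = 0.00812, and 0.183 with an estimated correlation). Plasma cell markers fell in 3 of 7 (4 adjusted over the list alone), Jchain at least 25.9-fold, with a median of -1.33 [-1.25, -1.37], or -1.05 at bounds (adjusted p = 0.00686, and 0.183 with an estimated correlation). Fibroblast and stromal markers, in contrast, rose in 11 of 19 cases and fell in 1 (13 and 3 adjusted over the list alone). Col1a1 rose by 3.90 ± 0.51, Fbln1 by 3.14 ± 0.34, Col1a2 by 2.74 ± 0.34 and Col5a1 by 2.64 ± 0.28. The stromal median was 1.5 [0.62, 1.84] (adjusted p = 0.00809, and 0.537 with an estimated correlation). Endothelial markers rose in 7 of 18 cases and fell in 1 (7 and 1 adjusted over the list alone), with Egfl7 at 2.10 ± 0.34, and the list was not called (adjusted p = 0.0792). Macrophage and myeloid markers fell in 3 of 17 (3 adjusted over the list alone) and were not called (adjusted p = 0.0508), but were with the spike-in set as a block (adjusted p = 0.0251). That call was lost with an estimated correlation (adjusted p = 0.555 with the block and 0.537 without).

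Several response lists were lower. Interferon response genes fell in 9 of 25 cases and rose in 1 (9 and 1 adjusted over the list alone), Oasl2 by -2.92 ± 0.22 and Ifit1 by -2.46 ± 0.22, with a median of -0.59 [-0.55, -0.61] (adjusted p = 0.00175, and 0.0614 with an estimated correlation). Immediate early and dissociation stress genes fell in 9 of 18 and rose in 2 (9 and 4 adjusted over the list alone), Nr4a1 by -4.08 ± 0.39 and Egr1 by -2.68 ± 0.17, with a median of -0.39 [-0.72, -0.33] (adjusted p = 0.0194, and 0.267 with an estimated correlation). Genes of STAT3 and cytokine response fell in 14 of 24 and rose in 4 (14 and 4 adjusted over the list alone), Il21r at least 21.5-fold lower and Il10 at least 11.3-fold higher, with a median of -1.14 [-0.86, -1.13], or -0.94 at bounds (adjusted p = 0.00686, and 0.25 with an estimated correlation). The cytotoxic lymphocyte list fell in 6 of 10 and rose in 1 (7 and 1 adjusted over the list alone), Ccl5 by -4.37 ± 0.34, with a median of -1.45 [-1.16, -1.64], or -0.77 at bounds (adjusted p = 0.00812, and 0.183 with an estimated correlation). In the BCL2 family 7 of 13 fell and 1 rose (8 and 1 adjusted over the list alone), Bcl2l1, an antiapoptotic member, by -1.97 ± 0.17 and Bik, a proapoptotic one, by 1.69 ± 0.23. Its median was -0.57 [-0.34, -0.72] (adjusted p = 0.0297, and 0.178 with an estimated correlation). Loci linked to SATB1 fell in 5 of 9 and rose in 2 (5 and 2 adjusted over the list alone), with Rag2, part of the V(D)J recombinase, at -3.19 ± 0.29 and a median of -1.41 [-1.98, -1.12] (adjusted p = 0.0212, and 0.137 with an estimated correlation). Cd8a, Cd4, Il7r and Rag2 also belong to the T cell lists. Of the 33 lists 21 were called in this comparison, 6 higher and 15 lower, and the 21 medians kept their sign within both spike-in sets and under quantile normalization, equal array medians and the offset of 50.

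**Figure D2:**
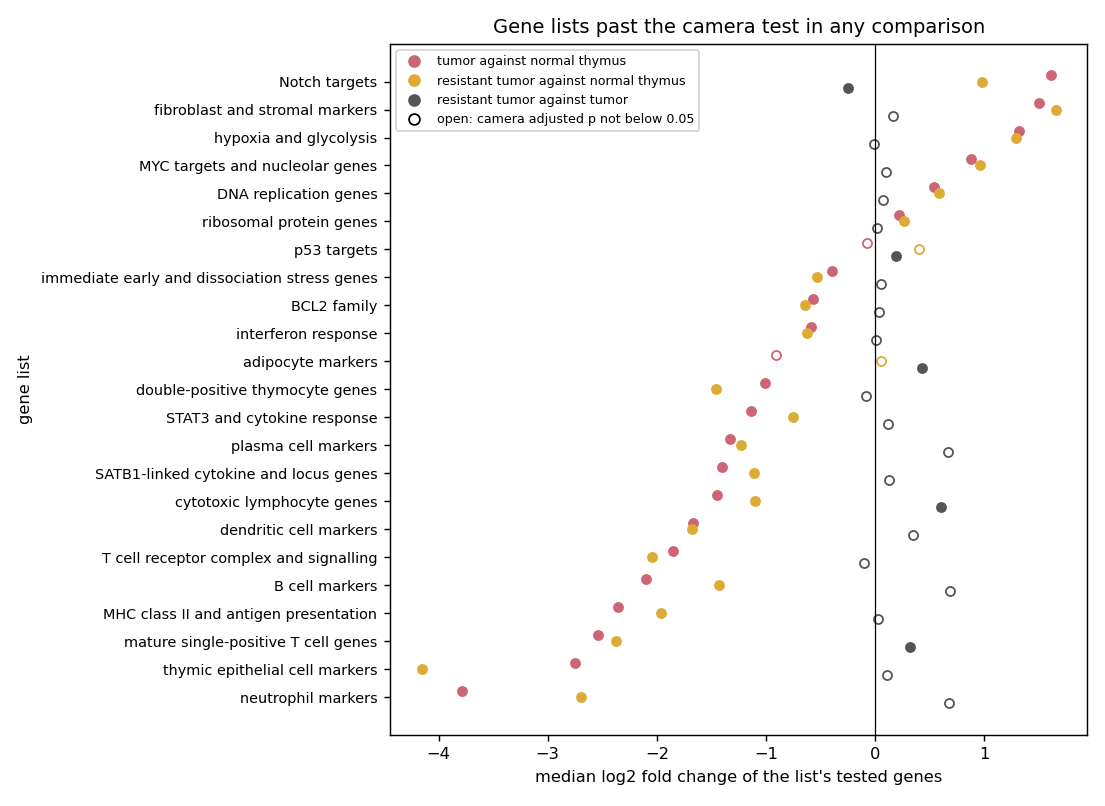
Median log2 fold change of the tested genes (horizontal axis) for each gene list called in any of the 3 comparisons, filled where the camera adjusted p was under 0.05 at the preset correlation and open otherwise. Thymic epithelial markers lie at -2.75 in tumor and -4.15 in resistant tumor against normal thymus (-2.75 and -2.85 with genes at their bounds) and at 0.11, not called, in resistant tumor against tumor, and fibroblast and stromal markers at 1.5 and 1.65.

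Against normal thymus, resistant tumors also had lower thymocyte and thymic epithelial genes. Cd8b1 was at least 131-fold, Cd8a at least 106-fold, Tbata at least 104-fold, Psmb11 at least 27.4-fold and Pax1 at least 19-fold lower, and Prss16 fell by -7.34 ± 0.81 on the log2 scale. Crip3 and Plekhb1 were at least 51.4-fold and 13.2-fold lower, Igkv8-30 and Fgf13 at least 52.3-fold and 15.7-fold. Adamts20 rose by 5.57 ± 0.24 and Fbp1 by 5.42 ± 0.29. Sall3 was at least 9.16-fold higher, Igfbpl1 at least 20.8-fold, Kcnk1 at least 3.93-fold, Crabp1 at least 6.57-fold, Olfm1 at least 6.66-fold and Trim9 at least 2.66-fold. By limma, 5049 genes were called, 2696 higher and 2353 lower, and 6862 with the spike-in set as a block. All 5049 had the same sign within both sets, which was fixed in advance for the 4968 calls whose groups did not overlap. Groups did not overlap in 54.6% of the tested genes, where chance gives 10%. Setting the array medians equal left 2034 calls, 878 higher and 1156 lower.

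The lists called against normal thymus were again 21, 6 higher and 15 lower, and all 21 medians had the same sign within both spike-in sets. Thymic epithelial markers fell in 18 of 21 cases and rose in 1 (19 and 1 adjusted over the list alone), with a median of -4.15 [-4.55, -4.34], or -2.85 at bounds (adjusted p = 1.11e-08, and 0.0442 with an estimated correlation, or 0.0726 with the spike-in set as a block as well). The T cell receptor list fell in 14 of 19 (14 adjusted over the list alone), with a median of -2.04 [-2.04, -1.57] (adjusted p = 1.46e-08, and 0.0224 with an estimated correlation, or 0.0726 with the spike-in set as a block as well). MYC targets and nucleolar genes rose in 22 of 23 and fell in 1 (22 and 1 adjusted over the list alone), with Cad at 1.72 ± 0.15 and a median of 0.96 [1.04, 0.88] (adjusted p = 1.46e-08, and 0.11 with an estimated correlation). B cell markers fell in 6 of 12 (6 adjusted over the list alone), with a median of -1.43 [-1.24, -2.32], or -1.09 at bounds (adjusted p = 0.00135, and 0.281 with an estimated correlation). Dendritic cell markers fell in 8 of 13 (8 adjusted over the list alone), with a median of -1.68 [-1.49, -1.59], or -0.70 at bounds (adjusted p = 0.00158, and 0.093 with an estimated correlation). Fibroblast and stromal markers rose in 13 of 19 and fell in 2 (14 and 2 adjusted over the list alone), with Fbln1 at 3.63 ± 0.34 and a median of 1.65 [0.96, 2.38] (adjusted p = 0.00147, and 0.425 with an estimated correlation). Notch targets rose in 8 of 13 and fell in 2 (9 and 2 adjusted over the list alone), with a median of 0.98 [1.07, 1.10] (adjusted p = 0.00424, and 0.205 with an estimated correlation). With the spike-in set as a block, STAT3 and cytokine response and immediate early genes lost their calls (adjusted p = 0.0651 and 0.0846), and endothelial and Y-linked genes gained one (adjusted p = 0.0463 and 0.041). These gained calls were lost with an estimated correlation (adjusted p = 0.498 and 0.329 with the block, 0.425 and 0.29 without). Of the genes called in both comparisons against normal thymus, 4185 had the same sign and 4 the opposite. Independent lists of these sizes would share 627 higher and 449 lower genes, against 2283 and 1902 observed. Both comparisons use the same normal arrays. Simulated unchanged groups gave a correlation of 0.501 across genes, which are not independent replicates, against 0.940 observed, a covariance of 0.0563 against 1.43, and 0 shared calls. The simulated covariance was at most 0.0609, which argues against the spread between the shared normal arrays as the main source of the excess. A deviation common to all normal arrays was not simulated, and these arrays were too few to split.

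Between resistant tumors and tumors, 42 genes were called, a count that changed with the fit. Plagl1, an imprinted zinc finger gene, rose from a signal of 112 ± 25.9 in tumors to 1266 ± 86.2 in resistant tumors (SD, n = 3), a log2 change of 3.52 ± 0.17 (limma adjusted p = 3.79e-05), and 3.88 and 3.42 within the arrays without and with spike-ins. Tox2, an HMG box factor gene, rose by 3.35 ± 0.40, Trat1, which encodes an adaptor of the T cell receptor, by 1.63 ± 0.20, and the T cell receptor gamma segment Trgv4 by 4.21 ± 0.60. Zfp503 rose by 2.35 ± 0.29, Sall3 by 1.97 ± 0.33 and Tubb2b by 1.68 ± 0.22, and Thrsp and Amigo2 were at least 2.02-fold and 4.40-fold higher. Rangrf fell by -3.53 ± 0.22 (adjusted p = 0.000172), Krtcap3 by -2.36 ± 0.19, Wtip by -2.08 ± 0.29 and Insyn2a by -1.98 ± 0.26. Pnck, a calcium/calmodulin-dependent kinase gene, was at least 4.61-fold lower (adjusted p = 0.000285). As3mt, an arsenite methyltransferase gene, was at least 5.23-fold lower, Vwce at least 3.23-fold, Ttc38 at least 1.74-fold and Scml2 at least 1.19-fold. Zfp286 was called lower (adjusted p = 0.0213), but its signals of 13.6 ± 2.17 in tumors and 0.579 ± 0.431 in resistant tumors (SD, n = 3) were too dim for a fold. Some calls were lost under other processing: with an offset of 50 before the log those of Thrsp, Amigo2 and Zfp286 (adjusted p = 0.144, 0.109 and 0.125), with quantile normalization those of Thrsp, Amigo2 and Wtip (adjusted p = 0.118, 0.0979 and 0.105), and with no filter those of Trgv4, Thrsp, Amigo2, Sall3, Scml2, Vwce, Wtip and Insyn2a (adjusted p = 0.0522 to 0.355). Without tumor 2, 14 of the 21 named genes lost their call. Of the 3 probe sets of Trgv4 past the filter 1 was called.

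In this comparison 42 genes were called by limma, 15 higher and 27 lower, and 844 had an unadjusted p under 0.05. With the spike-in set as a block there were 143 calls, 61 higher and 82 lower, which included all 42. All 42 had the same sign within both sets, which was fixed in advance because their groups did not overlap. The count also moved with the processing, to 22 with no filter, 23 with the stricter filter, 27 with the mean over probe sets and 8 with only the 2 groups in the fit. Array weights, whose iteration stopped before convergence, gave 3236 calls. The arrays with spike-ins, 1 of them a resistant tumor, gave 553, and those without, 1 of them a tumor, gave 1. The count rested on single arrays too: it was 8 without tumor 2, 10 without tumor 3, 20 without normal thymus 2, 19 without normal thymus 3 and 70 without resistant tumor 3. Setting the array medians equal moved the median change of all genes from -0.02 to -0.26 and left 4 higher and 14 lower calls. Groups did not overlap in 10.4% of the tested genes, where chance gives 10% if arrays are interchangeable. They were not, as the spike-in sets are spread unevenly over these groups. A gene that follows the sets could hardly separate them, so the share by chance may be lower and the closeness to 10% decides nothing.

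**Figure D3:**
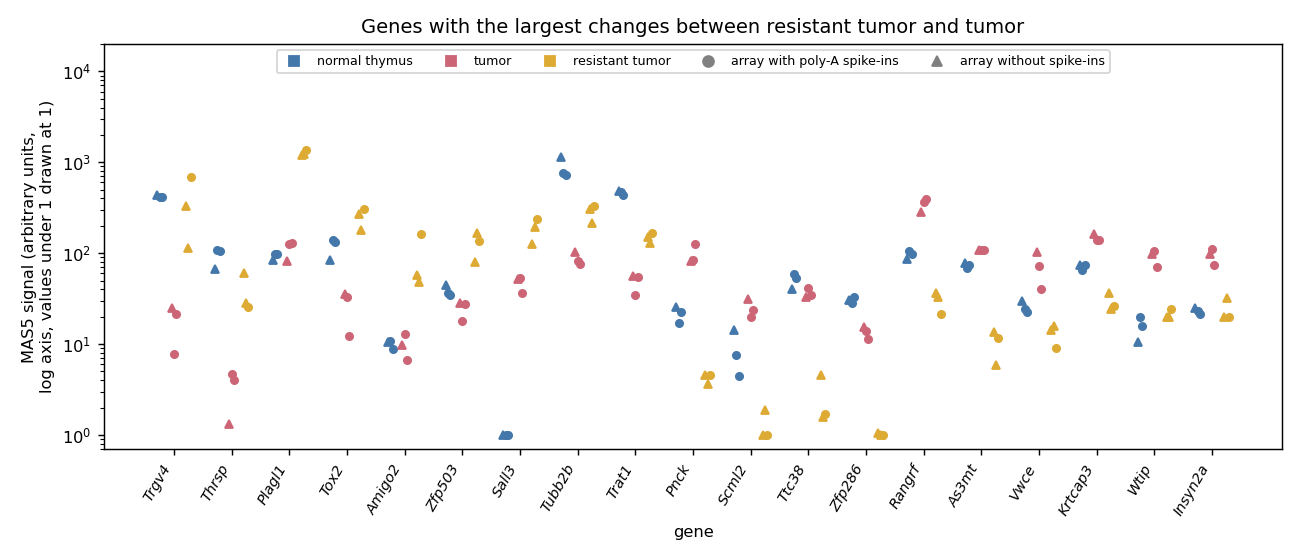
MAS5 signal (log axis, values under 1 drawn at 1) of the genes with the largest called changes between resistant tumor and tumor, 1 point per array, with colors for the group and symbols for the spike-in sets. Plagl1 had a mean signal of 1266 in resistant tumors, 112 in tumors and 92.9 in normal thymus.

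Of the 33 gene lists 5 were called between the tumor groups, and none with an estimated correlation (4 at an unadjusted p under 0.05 by camera). Notch targets were lower in resistant tumors, with a median log2 change of -0.25 [-0.21, -0.45] (adjusted p = 3.12e-05, and 0.243 with an estimated correlation). Of its 13 genes Heyl was the 1 called, at -1.98 ± 0.25 (4 lower adjusted over the list alone). Genes of mature single-positive T cells had a median of 0.32 [0.37, 0.50] (adjusted p = 0.00541, and 0.353 with an estimated correlation) and cytotoxic lymphocyte genes 0.60 [0.31, 0.53] (adjusted p = 0.00541, and 0.353 with an estimated correlation), with 3 and 2 genes higher adjusted over the list alone and none over all genes. The p53 target list had a median of 0.19 [0.16, 0.19] (adjusted p = 0.0118, and 0.243 with an estimated correlation; 2 genes higher adjusted over the list alone), which lay 0.20 above the median of all genes. Equal array medians moved every gene by the same -0.25 in this comparison, so the list's median of -0.06 there reflects the scaling, and its distance from all genes stayed 0.20. Adipocyte markers had a median of 0.43 [0.67, 0.39] over 8 genes, none of them called over all genes or adjusted over the list alone (adjusted p = 0.0283, and 0.353 with an estimated correlation). List medians here keep fitted changes of genes too dim for a fold in both tumor groups. Examples are Ccr7 of the mature T cell list (2.94 ± 2.34 in tumors, 4.36 ± 4.09 in resistant tumors, SD) and Cidea of the adipocyte list (5.29 ± 6.04 and 3.92 ± 3.04). Such genes were not counted, so the sizes of these medians are uncertain. The 5 calls became 2 without resistant tumor 3, 8 without resistant tumor 1 and 10 without resistant tumor 2 or without tumor 2. With the spike-in set as a block 11 lists were called. These were the 5 and another 6, of which 3 hold markers of other cell types: macrophage and myeloid (adjusted p = 0.000134), fibroblast and stromal (adjusted p = 0.000223) and dendritic cell markers (adjusted p = 0.0335), all higher. With an estimated correlation these 3 were not called (adjusted p = 0.429, 0.509 and 0.412 with the block, 0.665, 0.718 and 0.353 without). Their medians within the arrays without and with spike-ins were [0.34, 0.43], [0.52, 0.46] and [-0.30, 0.80], so that of dendritic cell markers differed in sign. The remaining 3 were STAT3 and cytokine response and MYC targets, both higher (adjusted p = 0.00772 and 0.00967), and double-positive thymocyte genes, lower (adjusted p = 0.0395), none of them called with an estimated correlation (adjusted p = 0.412, 0.429 and 0.396 with the block). Ighm, a B cell marker, fell by -1.0 ± 0.15 in a list that was not called (adjusted p = 0.106), and its own call was lost with no filter (adjusted p = 0.102). Thymic epithelial markers had a median of 0.11 [-0.05, 0.30] and were not called (adjusted p = 0.348).

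Xist, named in the labels, was higher in both tumor groups than in normal thymus. Its brightest probe set on average, which stood for the gene, had a signal of 24.9 ± 12.1 in normal thymus, 472 ± 127 in tumors and 406 ± 135 in resistant tumors (SD, n = 3). The log2 change was 4.31 ± 0.36 [3.70, 4.61] in tumors (adjusted p = 1.60e-05) and 4.07 ± 0.36 [3.09, 4.92] in resistant tumors (adjusted p = 2.31e-05). Between resistant tumors and tumors it was -0.23 ± 0.36 [-0.61, 0.31] and was not called (adjusted p = 0.893, or 0.785 with the spike-in set as a block). The other Xist probe sets gave values of the opposite sign for that difference, none of them called. The dimmer had signals of 7.44 ± 7.50, 65.5 ± 78.0 and 438 ± 395 in normal thymus, tumors and resistant tumors. Its difference between resistant tumors and tumors was 2.93 ± 1.15 [1.83, 2.18] (adjusted p = 0.918), or 2.04 with the spike-in set as a block (adjusted p = 0.224). The dimmest did not pass the filter. It reached the array median on 1 of 3 resistant arrays and on 0 of 3 tumor and 0 of 3 normal arrays, which leaves a bound of at least 1.75-fold for that difference, not called (adjusted p = 0.951). In tumors against normal thymus the dimmer was at least 2.02-fold higher, not called (adjusted p = 0.125) except with the block (adjusted p = 0.0017), and the dimmest was too dim for a fold (adjusted p = 0.22). In resistant tumors against normal thymus both were called, the dimmer at least 15.4-fold (adjusted p = 0.00873) and the dimmest at least 1.54-fold higher (adjusted p = 0.026). The Y-linked gene Eif2s3y had signals of 495 ± 29.7 in normal thymus, 337 ± 12.6 in tumors and 342 ± 23.7 in resistant tumors (SD, n = 3), so no group lacked it. Satb1, a chromatin organiser of thymocytes, fell by -1.31 ± 0.13 [-1.43, -1.24] in tumors (adjusted p = 5.28e-05) and by -1.72 ± 0.13 [-1.92, -1.68] in resistant tumors (adjusted p = 1.03e-05). The other 4 Satb1 probe sets also fell, by -1.57 ± 0.18 to -2.93 ± 0.65 in tumors and by -2.03 ± 0.18 to -4.00 ± 0.18 in resistant tumors, all of them called. The signal of the probe set that stood for the gene was 3215 ± 451 in normal thymus, 1302 ± 188 in tumors and 967 ± 43.1 in resistant tumors. The difference of -0.42 ± 0.13 [-0.48, -0.44] between the tumor groups was not called (adjusted p = 0.383), nor was the -0.48 with the spike-in set as a block (adjusted p = 0.0614). The other Satb1 probe sets ran from -1.5 ± 0.18 (adjusted p = 0.0759) to 0.11 ± 0.65 for that difference, none of them called in the fit of all probe sets. With the spike-in set as a block the highest of these values was -0.40 (adjusted p = 0.514) in place of 0.11, and all 5 probe sets had values below 0 within both sets. The p-values of the other Xist and Satb1 probe sets were adjusted over all probe sets without the filter, unlike those of the genes called above. In that fit the Satb1 probe set that stood for the gene had an adjusted p of 0.779 in place of 0.383. A probe set not called there could still have been called at the threshold used for genes. For Satb1, the -1.50 ± 0.18 above and the -0.50 ± 0.07 of another probe set (limma adjusted p = 0.135) were several times their SE. The absence of a call therefore does not show that Satb1 was equal in the tumor groups.

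**Figure D4:**
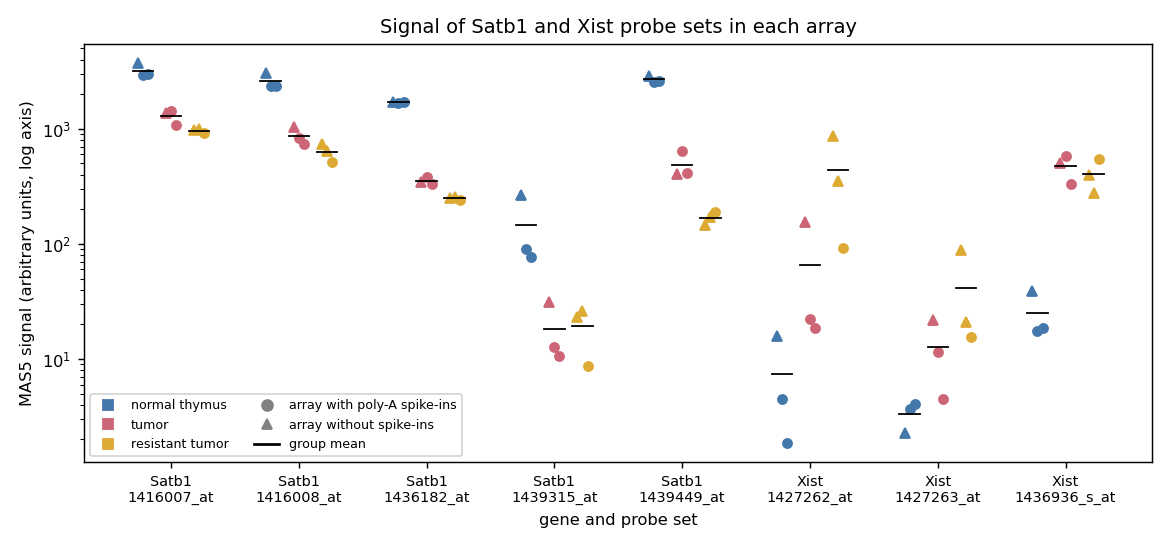
MAS5 signal (log axis) of each probe set of Satb1 and Xist in each array, with lines at the group means, colors for the group and symbols for the spike-in sets. The Satb1 probe set that stood for the gene has means of 3215 in normal thymus, 1302 in tumors and 967 in resistant tumors, and the 3 Xist probe sets differ in how the tumor groups compare.

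Genes of the X chromosome were tested as a group because the labels name XIST. The 338 tested genes had a median log2 change that differed from that of other genes by -0.11 [-0.05, -0.16] in tumors against normal thymus (adjusted p = 0.859), by -0.15 [-0.11, -0.19] in resistant tumors against normal thymus (adjusted p = 0.826) and by -0.0044 [-0.05, -0.04] in resistant tumors against tumors (adjusted p = 0.842). With the spike-in set as a block the last value was -0.04 (adjusted p = 0.434). No X chromosome shift was called by camera. In the fixed list of X-linked genes 9 of 45 rose and 7 fell in tumors against normal thymus (9 and 5 adjusted over the list alone), with Tsc22d3 at -2.07 ± 0.15 and Flna at -1.17 ± 0.17, and the list was not called (adjusted p = 0.64). The moderated F test over the 3 groups called 4925 genes, and 7009 with the spike-in set as a block.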

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

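The tests of the spike-in sets and of the marker lists below were chosen after the results were seen, and the counts over other splits of the arrays were planned. Probe sets to which the gene table gives no single symbol were outside the comparisons above. At the level of probe sets, 1201 of 3956 of them were called in tumor against normal thymus, 2 in resistant tumor against tumor and 1256 in resistant tumor against normal thymus.

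For a pair of groups the 6 arrays make 10 splits, too few for a share under 0.05. In tumor against normal thymus the real split called 4943 genes and the highest other split 0 by limma, with 749 at an unadjusted p under 0.05, and 1 split reached the real count. In resistant tumor against normal thymus these were 5049 and 0, with 1660 unadjusted, and again 1 split reached the real count. In resistant tumor against tumor the real split called 42 genes and the highest other split 3242, so 2 splits reached the real count. That split set resistant tumor 1, resistant tumor 2 and tumor 1 against the rest, which is the split along the spike-in sets, and its count points to a structure of the arrays. The remaining 8 splits called 0 genes, with at most 751 unadjusted. With the set as a block the real split called 143 genes and the highest of the other splits that could be fitted called 0, with at most 1240 unadjusted. For the F test, 1 of 100 splits drawn from the 280, the real one, gave as many genes as the real 4925. As the arrays may be technical, this rank says nothing about chance between animals. The highest other split gave 4907. It kept the normal arrays together, as did 5 of the 100 in all, the real one included, with 4506 genes or more. The splits that did not called at most 1. The F test count thus follows normal thymus against the rest and says little about the difference between the tumor groups.

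The sets of arrays with and without spike-in signal could have made the calls between resistant tumors and tumors. If so, most calls would end once the set was a block, yet 42 of 42 kept their sign and their call. This does not decide the question, since both tumor groups held arrays of both sets. A gene that followed the sets would spread within its group and could hardly have been called without the block. The sets do add to the spread, since the block raised the count to 143. Differences between the tumors other than resistance stay open and were not tested.

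Lists of thymic epithelial, B cell and dendritic cell markers were called lower in both tumor groups, but with an estimated correlation B cell and dendritic lists were not (adjusted p = 0.183 and 0.0614 in tumors, 0.281 and 0.093 in resistant tumors). Fewer cells of every kind other than T cells would lower fibroblast and stromal markers too, yet their median was at least 0.62 in each spike-in set and tumor group, and fry found them higher on balance (adjusted p = 0.018 in tumors and 0.0105 in resistant tumors). That argues against this explanation, although camera's call of this list against other genes was lost with an estimated correlation (adjusted p = 0.537 and 0.425). The spike-in sets are argued against too, since the epithelial median was at most -2.39 in each set and tumor group. A lower share of epithelial cells, lower expression in them and a change in stromal cells may each contribute and were not told apart.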

How the results depend on the processing

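Fits with the spike-in set as a block or within 1 set were chosen after seeing the data. Except where a smaller or larger number of genes or arrays is named, the cause was not tested. Equal array medians gave 2287 genes in tumor against normal thymus, 18 in resistant tumor against tumor, 2034 in resistant tumor against normal thymus and 2069 in the F test. All probe sets gave 8638 and 8880 in tumor and resistant tumor against normal thymus and 8442 in the F test, where more features were tested. Array weights, whose iteration stopped before convergence, gave 7557, 3236, 8415 and 9505, so that between the tumor groups depends on them most. A minimum change of 1 gave 2529 and 2503 in the comparisons with normal thymus. Arrays without spike-ins alone, 4 in number, with 1 normal and 1 tumor array assumed to vary like the rest, gave 2117, 1, 3069 and 2204, and the 5 with them, with 1 resistant array under the same assumption, gave 553 in resistant tumor against tumor. That comparison also had 22 calls with no filter, 23 with the stricter filter, 27 with the mean over probe sets, 8 with only the 2 groups in the fit and 143 with the spike-in set as a block. Left-out arrays gave 8 to 70 there, 3878 to 5374 in tumor against normal thymus, 3818 to 5310 in resistant tumor against normal thymus, 3502 to 5345 in the F test and 3200 to 4133 for the overlap. A group left with 2 arrays shares the spread of the others.

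Whether replicate numbers pair the arrays could not be told apart from the spike-in sets. Of pairs with the same number 7 of 9 correlated over 0.1, with -0.337 as the lowest, against 6 of 18 pairs with other numbers. Within a spike-in set 13 of 13 pairs correlated over 0.1, and across the sets 0 of 14 did. As a block the replicate number gave 92 calls in resistant tumor against tumor and 9 lists. With an estimated correlation 2 lists were called in each comparison with normal thymus and 0 in resistant tumor against tumor, where camera gave 4 at an unadjusted p under 0.05, fry 2 and the spike-in block 11. With the block and an estimated correlation together camera called 0 in each comparison, with 10 lists in tumor and 7 in resistant tumor against normal thymus and 2 in resistant tumor against tumor at an unadjusted p under 0.05. Left-out arrays gave 2 to 10 lists in this comparison, 21 to 23 in tumor and 18 to 23 in resistant tumor against normal thymus. Fry, which tests against no change and not against other genes, called X chromosome genes as a set in tumors (adjusted p = 0.0413) and in resistant tumors (adjusted p = 0.0166) against normal thymus, where their shifts from other genes were -0.11 and -0.15. Left-out arrays moved these shifts from -0.18 to -0.08 and from -0.17 to -0.11, and that between the tumor groups from -0.06 to 0.04. Of the other probe sets of Xist, 1 gave a bound of at least 1.01 on the log2 scale in tumors, uncalled, and the other was too dim for a value. With left-out arrays Xist ran from 4.10 to 4.68 in tumors, from 3.84 to 4.45 in resistant tumors and from -0.47 to 0.02 between them, and Satb1 from -1.38 to -1.18, -1.79 to -1.61 and -0.54 to -0.34.

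Named genes and called lists were refitted with quantile normalization, the offset of 50, no filter, the replicate number or spike-in set as a block and left-out arrays, and lists also with fry and an estimated correlation. In these no gene's change and no list's test turned its direction. Of 3808 values for genes 230 lost the call, and of 799 for lists 120 did. Of the 21 genes named for resistant tumor against tumor, 7 were called in every alternative run for them: As3mt, Krtcap3, Plagl1, Pnck, Rangrf, Tox2 and Trat1. The other 14 each lost the call without tumor 2 and under at least one further alternative. Low signals limit the values of dim genes, with 5.48% to 14.5% of the values of an array under 1.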

Other observations

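All tests of chromosome 15 were chosen after the result was seen. Outside the lists described so far, Tet2, which encodes a DNA demethylase, fell by -2.67 ± 0.30 in tumors and by -2.40 ± 0.30 in resistant tumors against normal thymus. Dnmt3b, a DNA methyltransferase gene, rose by 1.16 ± 0.18 and 1.01 ± 0.18, and Phc1 fell by -1.25 ± 0.31 and -1.77 ± 0.31. Among p53 targets 7 of 17 rose and 8 fell in tumors, Zmat3 by 1.57 ± 0.17 and Fas, a death receptor gene, at least 10.2-fold lower, and the list was not called (adjusted p = 0.585). In the list of Polycomb and DNA methylation genes 9 of 27 rose and 5 fell in tumors, and the list was not called (adjusted p = 0.86). Of 3 Y-linked genes tested, Kdm5d and Eif2s3y fell in tumors by -0.86 ± 0.19 and -0.56 ± 0.10, and the list was not called (adjusted p = 0.0792).

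Genes of chromosome 15 were higher in resistant tumors than in tumors. Their median change exceeded that of other genes by 0.25 over 459 genes, and 86.5% of them had a change above 0, against 46% of other genes. With left-out arrays the shift was 0.38 without resistant tumor 1 and 0.15 without resistant tumor 3. Camera gave an adjusted p of 6.64e-17 at the preset correlation, but 0.582 with an estimated correlation of 0.169, or 0.731 with the spike-in set as a block as well, so the call depends on how far genes of a chromosome move together. Fry, which tests the chromosome's genes against no change and not against other genes, gave an adjusted p of 0.302. Against the normal arrays of the same spike-in set the shift was 0.01 in resistant tumor 1, 0.31 in resistant tumor 2 and 0.42 in resistant tumor 3, and -0.05, -0.02 and -0.02 in tumors 1, 2 and 3. Other chromosomes ran from -0.22 to 0.12 in these arrays. In resistant tumor against normal thymus the shift was 0.22 and was not called (adjusted p = 0.237).

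Against the spike-in sets as the source, the shift was 0.31 with the set as a block, and 0.20 and 0.45 within the arrays without and with spike-ins. Expression level alone is argued against, since 0 of 10000 random gene sets matched on mean expression reached the chromosome's median of 0.22, with 0.03 as the highest. Those sets drew genes from outside the chromosome, which need not move together as genes of a chromosome may. The count is therefore no measure of chance for a chromosome singled out after the result was seen. A few strongly changed genes are argued against as well, since all 10 of 10 parts of the chromosome in gene order lay above 0.1. In resistant tumor against tumor, without the block, the largest shift of any other chromosome was 0.0597 in size. Chromosome 15 was singled out because its shift was the largest, so smaller shifts elsewhere were known beforehand. An extra copy of the chromosome in cells of some resistant tumors may explain the shift as a hypothesis, which these values do not test. Limits are that 3 copies against 2 would give 0.58 in all cells, that resistant tumor 1 does not show it, that parts of the chromosome lay near 0 against normal thymus (0.03 to 0.53 in resistant tumor 2 and 0.00 to 0.77 in resistant tumor 3), and that Myc, a gene of this chromosome, had a change of -0.29 ± 0.12 (adjusted p = 0.653). The parts nearest 0 lay at the 2 ends of the chromosome and were lower still in tumors 1, 2 and 3. There part 1 gave -0.22, -0.57 and -0.34, and part 10 gave -0.24, -0.18 and -0.24.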
